A study of Mus musculus with 3 samples.

How the data were processed

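Nuclei of cerebellar granule cells were isolated on a density cushion and sorted for high GFP and for singlets from a Neurod1 EGFP-Rpl10a reporter mouse line, per the labels' protocols. RNA was extracted with DNase digestion, amplified to cDNA with an Ovation RNA-Seq kit and made into TruSeq libraries, per the labels' protocols. Amplification precedes library construction and no molecular identifiers are mentioned, so reads are not independent molecules, and all intervals and floors cover counting error only. The labels give 3 replicate libraries in 1 group, so the design holds no comparison between groups of samples. The submitters' processing notes name STAR 2.4.2a, SAMtools, HOMER 4.8 and the build mm10, without saying what each was used for. Filters, strand settings and the treatment of multiply mapped reads are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart.

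The authors deposited RPKM values (reads per kilobase of span, scaled to the depth of the library) in 1 column for the 3 libraries together, with a row for each of 31161 RefSeq transcripts of 22685 gene symbols. All values (100%) were multiples of 1/3000, as a mean of 3 values with 3 decimals would be. Of 3382 spans listed for more than 1 transcript, 3140 held 1 value for all of them, so the unit of counting was the whole span from start to end, and RPKM of the authors divides by that span. A second deposited table gives a score named effect size for the authors' comparison of Dnmt3a conditional knockout and wild type. That score is never negative and how it was made is not given in the sources used here. The 2 other value columns of that table are means of samples outside the 3 libraries and were not used. No transcript lay on the X, Y or mitochondrial chromosome, and those chromosomes were not analysed here. Coordinates are 1-based on mm10. Of the transcripts used, 98.7% were found by accession in a RefSeq gene table of the same build, and 97.5% of these lay within the gene of that table.

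Each gene was represented by its transcript with the longest span. Before that, 95 transcripts whose span exceeded 3 times that of the reference gene were left out, since they join several loci of multi-copy small RNAs and repeats in 1 row. Both choices were made after seeing the data, and 22595 genes remained. A gene was called nested when its span lay within that of another gene. Depth was recovered from spans of at most 500 bp, where values multiplied by span fell on 3 steps, the worth of 1 read in each library. The steps were 0.0262, 0.0330 and 0.0386 reads per M reads (M, 1000000), which correspond to 38.2, 30.3 and 25.9 M reads, though not to known libraries. Of 209 low values of short spans, 97.6% were sums of whole reads within 0.0006 reads per M reads, against 28.2% expected of evenly spread values. The approximate read number of a gene is its RPKM times its span in kb times 94.4, the total depth in M reads, which assumes a like rate in the 3 libraries. From it came 95% Poisson intervals and a floor of 3 counts. Ratios of family members carry an interval from both read numbers.

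Before the data were examined, the gene lists, the floor of 1 RPKM, the pseudocount of 1 RPKM and the rule for named genes were fixed. The rule takes the 20 highest genes, the 4 highest and the lowest member of each list, all DNA methyltransferase, TET and methyl-CpG reader genes, and Rpl10a and Neurod1. Parts of the rule on genes that vary between libraries and on fold changes of the knockout comparison could not be applied. A few genes outside the rule are named, and were chosen after their values were seen: next-ranking members beside the 4 highest, Mki67, Grin2b, members of counts of 5 or fewer, long genes and genes of the effect size table. The lists cover mature, progenitor and newborn granule cells, Purkinje cells, GABAergic interneurons, unipolar brush cells, astrocytes and Bergmann glia, oligodendrocytes and their precursors, microglia, endothelial and mural cells, red blood cells, choroid plexus and forebrain neurons. Others hold DNA methylation genes, MeCP2 partners, receptors, channels, synaptic genes, immediate early, heat shock, clock, housekeeping, noncoding RNA, ribosomal, respiratory, proteasome, SR factor, Hox, receptor, protocadherin, histone, small nucleolar RNA and microRNA genes. Some genes stand in more than 1 list, such as Gabra6, Gabrd, Grin2c and Kcnd2 among granule cell and receptor or channel genes.

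The planned tests across libraries, agreement between libraries, variation between libraries and the requirement of expression in every library could not be carried out on a pooled mean, so the floor was applied to the mean. A list median of log2(RPKM + 1) was ranked among 10000 random lists of the same size, drawn from all genes or matched on span in 10 bins, which describes these libraries and is not a test. Differences between list medians have 95% bootstrap intervals over list members (2000 draws), used only to judge how far an alternative moved them. The alternatives were pseudocounts of 0.1 and 0.01, floors of 0.1 and 5 RPKM, means in place of medians, other backgrounds, values not divided by span, other transcripts per gene, merged loci kept, and lists without nested genes. On simulated data, the depth steps were recovered within 0.044%. Simulated lists of 10 genes were drawn among 12007 genes at 0.1 RPKM or more and ranked only against those genes, matched on span. Of 20 such lists, 0 reached percentile 97.5 with no change, 11 with 2-fold and 20 with 4-fold higher values. They do not show how often unchanged lists of expressed genes reach that percentile among all genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.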

Results

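Nuclear RNA was measured in cerebellar granule cells of the mouse, the small excitatory neurons that make up most of the cells of the cerebellum. Nuclei were sorted by green fluorescence from a mouse line in which Neurod1 regulatory sequence drives an EGFP-tagged ribosomal protein L10a (Rpl10a). The series holds 3 replicate libraries of GFP-positive nuclei, which form 1 group, and the study addressed cytosine methylation and hydroxymethylation in these cells and MeCP2 binding. The values analysed are the authors' mean RPKM over the 3 libraries, counted over the whole transcribed span of each RefSeq transcript, exons and introns together. No value of a single library was used, so no SD, n or test between libraries can be given, and nothing states whether the libraries came from separate animals. The step sizes of low values corresponded to depths of 38.2, 30.3 and 25.9 M reads (M, 1000000), 94.4 M in all. The 95% intervals given with single genes are Poisson intervals from the approximate read number behind each mean, and they cover counting error only.

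The nuclear transcript Malat1, a long noncoding RNA retained in the nucleus, had the highest level at 1738 RPKM (95% interval 1735 to 1742; chromosome 19, 5795690 to 5802671, minus strand, build mm10). It was followed by the ribosomal RNA precursor Rn45s at 629 RPKM and by a span of 123 bp annotated as the microRNA gene Mir6236 at 405 RPKM. The highest protein-coding genes were Cbln3 at 151 RPKM and Cbln1 at 65.2 RPKM, which encode cerebellins, synaptic organizers secreted by granule cells, and Atp1b2 at 68.8 RPKM, a sodium-potassium ATPase subunit. Gabra6, the GABA-A receptor α6 subunit typical of granule cells, reached 38.6 RPKM (38.2 to 38.9; chromosome 11, 42306437 to 42321072, minus strand). The 20 highest genes also held Ackr1 at 56.6 RPKM, Prrt2 at 33.7 RPKM, the RNA helicase gene Ddx5 at 34.7 RPKM, the splicing factor gene Srsf2 at 31.8 RPKM and the noncoding RNAs A930011O12Rik at 54.2, Snhg11 at 32.4 and Meg3 at 31.8 RPKM. The short gene Gm20594 (334 bp) stood at 50.8 RPKM. The treatment of multiply mapped reads is not given, so whether the reads over Mir6236 and Gm20594 came from those genes is unknown. Several of the top 20 lay inside another gene and cannot be told apart from its reads. Mir1906-1 (99.3 RPKM) and Mir1906-2 (99.7 RPKM) lay at the same position in Meg3, Mir3064 (74.8 RPKM) in Ddx5, Mir29c (94.6 RPKM) in A330023F24Rik, and Peg3os (35.7 RPKM) on the opposite strand of Peg3, which stood at 16.3 RPKM. Of 22595 genes, 5391 (23.9%) reached 1 RPKM. At a floor of 0.1 RPKM the number was 12007 (53.1%) and at a floor of 5 RPKM it was 434 (1.92%). A further 2955 genes (13.1%) were listed at 0.

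As a list, markers of the mature granule cell stood above those of the 13 other cell types and stages examined. The 19 mature granule cell genes had a median of 10.5 RPKM, and 18 of them reached 1 RPKM. Cbln3, Cbln1, Gabra6 and Neurod1 (21.4 RPKM, a transcription factor whose regulatory sequence drives the sort transgene) were the highest, and Zic4 was the lowest at 0.845 RPKM. The median stood at percentile 100 of 10000 random lists of the same size. The 12 genes of proliferating granule cell progenitors had a median of 0.00883 RPKM, at percentile 1.51. The percentile was 2.58 with the mean over members in place of the median, and 11.9 when values were not divided by span. Atoh1, the transcription factor of the rhombic lip lineage, was listed at 0, and the cycling gene Mki67 stood at 0.0243 RPKM. Ptch1, the Sonic hedgehog receptor gene, was the exception at 2.96 RPKM, followed by Ccnd1 at 0.301 and Top2a at 0.031 RPKM. Genes of newborn or migrating granule cells lay between, with a median of 0.739 RPKM (percentile 89.5) and 4 of 9 at 1 RPKM or more. Cntn2 stood at 6.85 RPKM, Barhl2 at 2.91, Unc5c at 2.54 and Sema6a at 1.74 RPKM, while Nhlh1 stood at 0.002 RPKM. On the log2(RPKM + 1) scale, which understates differences between low genes, the mature granule cell median exceeded the progenitor median by 3.51 and the newborn median by 2.73.

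Lists of other neurons lay below the granule cell list but differed in their place among random lists. The 11 Purkinje cell genes had a median of 0.354 RPKM, 3.09 log2 units below the granule cell median and at percentile 71.0. Rgs8 stood at 4.37 RPKM, Pcp2 at 1.43, Itpr1 at 0.455 and Slc1a6 at 0.431 RPKM, and Skor2 was the lowest at 0.00933 RPKM. None of the 13 GABAergic interneuron genes reached 1 RPKM, that is 0 of 13, with a median of 0.027 RPKM at percentile 15.8, and at 0.11 with the mean over members. Their highest members were Slc32a1, the vesicular GABA transporter gene, at 0.234 RPKM, Gad1 at 0.137, Kit at 0.112 and Tfap2b at 0.099 RPKM. The unipolar brush cell list came closest to the granule cell list, with a median of 2.12 RPKM and a difference of 2.001 log2 units, and lay at percentile 98.67 of random lists (97.09 of lists matched on span and 96.2 with the mean over members). It holds 4 genes, of which Grm1 (3.45 RPKM) also belongs to the metabotropic glutamate receptors. Plcb4 stood at 3.32 RPKM, Eomes at 0.916 RPKM and Lmx1a at 0.0537 RPKM. Forebrain neuron genes had a median of 0.00817 RPKM (3.51 log2 units below, percentile 1.36). The percentile was 7.77 among genes above 0 and 6.58 when values were not divided by span. Prox1 stood at 1.94, Wfs1 at 0.341 and Ppp1r1b at 0.161 RPKM, and Fezf2 was listed at 0.

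**Figure D1:**
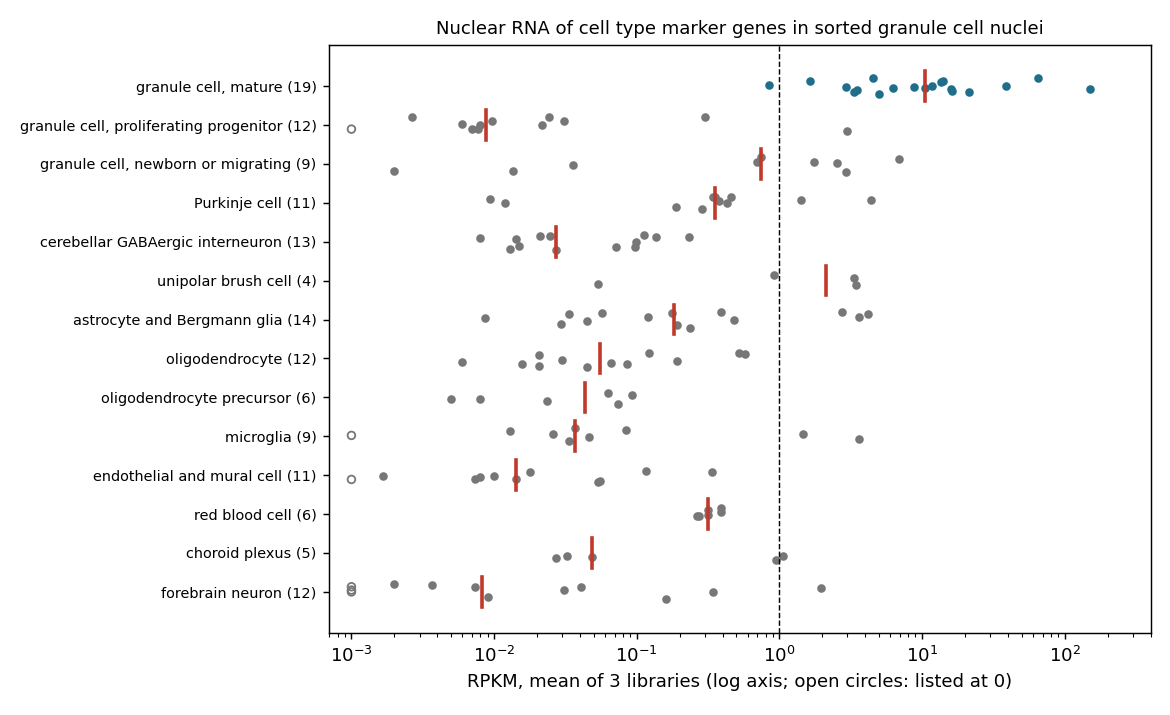
Each point is a marker gene, placed by its RPKM as the authors' mean of 3 libraries on a log axis, with the number of measured genes beside each list name. Red bars are list medians, the dashed line marks 1 RPKM and open circles are genes listed at 0. The mature granule cell median lies at 10.5 RPKM, and the next highest, of 4 unipolar brush cell genes, at 2.12 RPKM.

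Glial, vascular, blood and choroid plexus lists also lay below the granule cell list, and none of their medians stood apart from random lists of all genes. With means over members, oligodendrocytes (1.37), their precursors (1.77) and endothelial and mural cells (0.17) lay in the lowest 2.5% of random lists. The 14 astrocyte and Bergmann glia genes had a median of 0.183 RPKM (3.28 log2 units below the granule cell list, percentile 50.15), with 3 members above 1 RPKM. These were the bicarbonate transporter gene Slc4a4 at 4.20 RPKM, Aldoc at 3.61 RPKM and Timp4 at 2.77 RPKM. Timp4 lies on the opposite strand inside Syn2, itself at 3.22 RPKM, so its reads cannot be separated from those of Syn2. Slc1a2 stood at 0.482 RPKM and Aldh1l1 was the lowest at 0.00867 RPKM. Among 12 oligodendrocyte genes the median was 0.0553 RPKM (3.45 log2 units below, percentile 25.2), with Mbp highest at 0.572, Cnp at 0.518 and Opalin lowest at 0.006 RPKM. The 6 oligodendrocyte precursor genes had a median of 0.0432 RPKM (3.47 below, percentile 23.15) and a highest member, Olig2, at 0.093 RPKM. The 9 microglial genes had a median of 0.037 RPKM (3.47 below, percentile 26.5). Hexb stood at 3.63 RPKM, P2ry12, which lies inside Med12l (1.83 RPKM) on the opposite strand, at 1.47 RPKM, and Trem2 was listed at 0. Endothelial and mural cell genes had a median of 0.0143 RPKM (3.51 below, percentile 6.65, but 1.78 of lists matched on span), with Vtn at 0.337, Tek at 0.116 and Cldn5 listed at 0. The 6 measured red blood cell symbols are globin genes at 3 loci, in pairs with the same or nearly the same span, so the members of a pair are not separate measurements. Their median was 0.316 RPKM (3.13 below, percentile 60.6, and 90.6 of lists matched on span). The 5 choroid plexus genes had a median of 0.0487 RPKM (3.46 below, percentile 34.9), with Otx2 at 1.06 and Ttr at 0.95 RPKM. No replicate spread or p-value is attached to these differences, because only the mean over the 3 libraries was used. All 13 differences kept their sign under each alternative computed. A change of pseudocount keeps the order of genes and so could scarcely reverse them. Leaving out nested members changed only lists that hold such members.

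Genes listed as writing, oxidizing or reading DNA methylation, the subject of the study, ranged from 0.0167 RPKM for Dnmt3l to 3.78 RPKM for Zbtb4. The median over all genes was 0.156 RPKM. Dnmt3a, a de novo DNA methyltransferase gene, stood at 1.83 RPKM (1.80 to 1.86; chromosome 12, 3806980 to 3914443, plus strand). This was 2.28 times the level of the maintenance methyltransferase gene Dnmt1 (0.804 RPKM; interval of the ratio 2.20 to 2.36) and 8.25 times that of Dnmt3b (0.222 RPKM; 7.69 to 8.86). The span of the shorter Dnmt3a transcript (chromosome 12, 3891744 to 3914443) had a higher density of reads, 2.81 RPKM. It is the 3' part of the longer span, so reads of either transcript count in it. The level of the shorter transcript alone cannot be told from this value. The shorter spans of Dnmt1 stood at 0.912 to 0.921 RPKM, with 3910 to 3978 reads against 3996 in the longest. The ratio of Dnmt3a to Dnmt1 thus depends on the span chosen, which its interval leaves out. Uhrf1, which recruits Dnmt1 to replicating DNA, stood at 0.0293 RPKM, and Dnmt3l at 0.0167 RPKM. The 5 genes of this list had a median of 0.222 RPKM, at percentile 55.5 of random lists. Of the dioxygenase genes that oxidize 5-methylcytosine, Tet3 (2.37 RPKM) exceeded Tet2 (0.897 RPKM) by 2.64 times (2.57 to 2.72) and Tet1 (0.728 RPKM) by 3.26 times (3.16 to 3.36). Cxxc5 stood at 2.41, Cxxc4 at 1.35, the thymine DNA glycosylase gene Tdg at 1.27 and Smug1 at 0.710 RPKM. The TET and base excision list had a median of 1.27 RPKM, with 4 of 7 measured genes at 1 RPKM or more. Tet3 was the only TET gene among these 4. The list lay at percentile 97.6 of random lists but at 94.96 of lists matched on gene span.

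Of the list named methyl-CpG readers, 9 of 11 genes were measured, since genes of the X chromosome, Mecp2 among them, were not analysed here. The list was drawn up by gene name, and binding of its members to methylated CpG was not examined. Their median was 1.44 RPKM, at percentile 99.3, and 7 reached 1 RPKM. Zbtb4 was highest at 3.78 RPKM (3.69 to 3.88), followed by Mbd6 at 1.98, Uhrf2 at 1.86, Mbd1 at 1.73, Mbd5 at 1.44, Mbd2 at 1.22 and Zbtb38 at 1.18 RPKM. Mbd4 stood at 0.593 and Mbd3 at 0.502 RPKM. The 8 measured corepressor partners of MeCP2 had a median of 1.55 RPKM, at percentile 99.6, with Gps2 at 4.16, Ncor1 at 3.32, Sin3a at 1.65 and Hdac3 at 1.64 RPKM, and Ncor2 lowest at 0.807 RPKM. Among genes at 1 RPKM or more, the readers (percentile 48.1) and the corepressor partners (37.8) no longer stood apart. The same held for the TET and base excision list (51.7). The ratios between family members rest on pooled means, so their intervals leave out the variation between libraries. All 4 ratios kept their direction, which a change of pseudocount cannot reverse. The Dnmt3a to Dnmt3b difference on the log2(value + 1) scale, 1.21 in RPKM, was 4.38 when values were not divided by span.

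**Figure D2:**
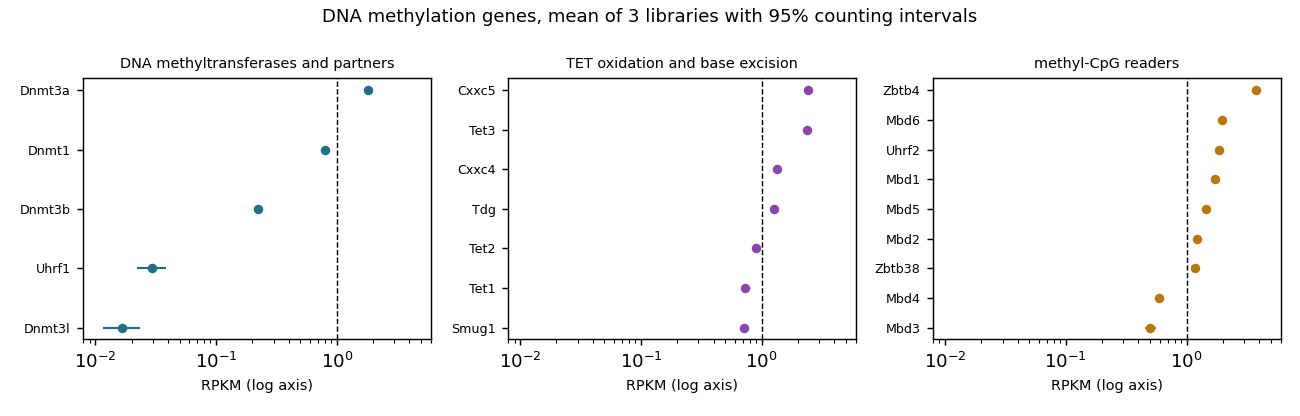
Points give RPKM on a log axis for DNA methyltransferase genes, TET and base excision genes and methyl-CpG reader genes, each as the authors' mean of 3 libraries. Horizontal lines are 95% Poisson intervals of the approximate read number, which cover counting error only, and the dashed line marks 1 RPKM. Dnmt3a lies at 1.83 RPKM, Tet3 at 2.37 RPKM and Zbtb4 at 3.78 RPKM.

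Levels of receptor and channel genes spanned a wide range within each family. Of 12 measured GABA-A receptor subunit genes, 6 reached 1 RPKM. Gabra6 stood at 38.6 RPKM, Gabrb2 at 4.97, Gabrd, the δ subunit of extrasynaptic receptors, at 4.57 and Gabra1 at 3.95 RPKM, whereas Gabra5 stood at 0.0113 RPKM. Of 17 ionotropic glutamate receptor genes, 7 reached 1 RPKM. The NMDA receptor subunit genes Grin2c (11.8 RPKM) and Grin1 (10.1 RPKM) were highest, with Gria2 at 3.62 and Grik2 at 3.60 RPKM. Grin2b, the NMDA subunit of immature granule cells, stood at 0.0137 RPKM, and Grid1 was the lowest at 0.0127 RPKM. Among 8 metabotropic glutamate receptor genes, Grm4 at 11.8 RPKM and Grm1 at 3.45 RPKM exceeded 1 RPKM, Grm3 stood at 0.152 RPKM, Grm2 at 0.027 and Grm6 at 0.00433 RPKM. The list medians of these 3 families were 0.555, 0.368 and 0.0258 RPKM, at percentiles 81.5, 75.2 and 15.6 of random lists. In the same order, the percentiles were 58.3, 47.3 and 4.40 of lists matched on span, and 99.85, 99.3 and 80.2 with means over members in place of medians.

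Potassium channel genes had a median of 0.887 RPKM over 30 measured members, at percentile 99.7. Kcna1 stood at 20.8, Kcnc3 at 16.3, Kcnd2, an A-type channel gene, at 16.2 and Kcnc1 at 13.7 RPKM, while Kcna4 was the lowest at 0.0113 RPKM. The 17 measured sodium and calcium channel genes had a median of 0.805 RPKM, at percentile 96.9 (99.3 with the mean over members), with Scn2a1 at 9.92, Cacna1a, the P/Q-type calcium channel gene, at 6.34, Scn8a at 3.47 and Cacna1c at 2.57 RPKM, and Scn10a at 0.00433 RPKM. Synaptic vesicle and adhesion genes were higher as a list, with a median of 2.70 RPKM, percentile 100 and 18 of 24 genes at 1 RPKM or more. Syt4 stood at 18.8, Snap25 at 17.6, Vamp2 at 12.3 and Nrxn1 at 6.25 RPKM. Stx1a, a syntaxin gene, stood at 0.0283 RPKM.

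**Figure D3:**
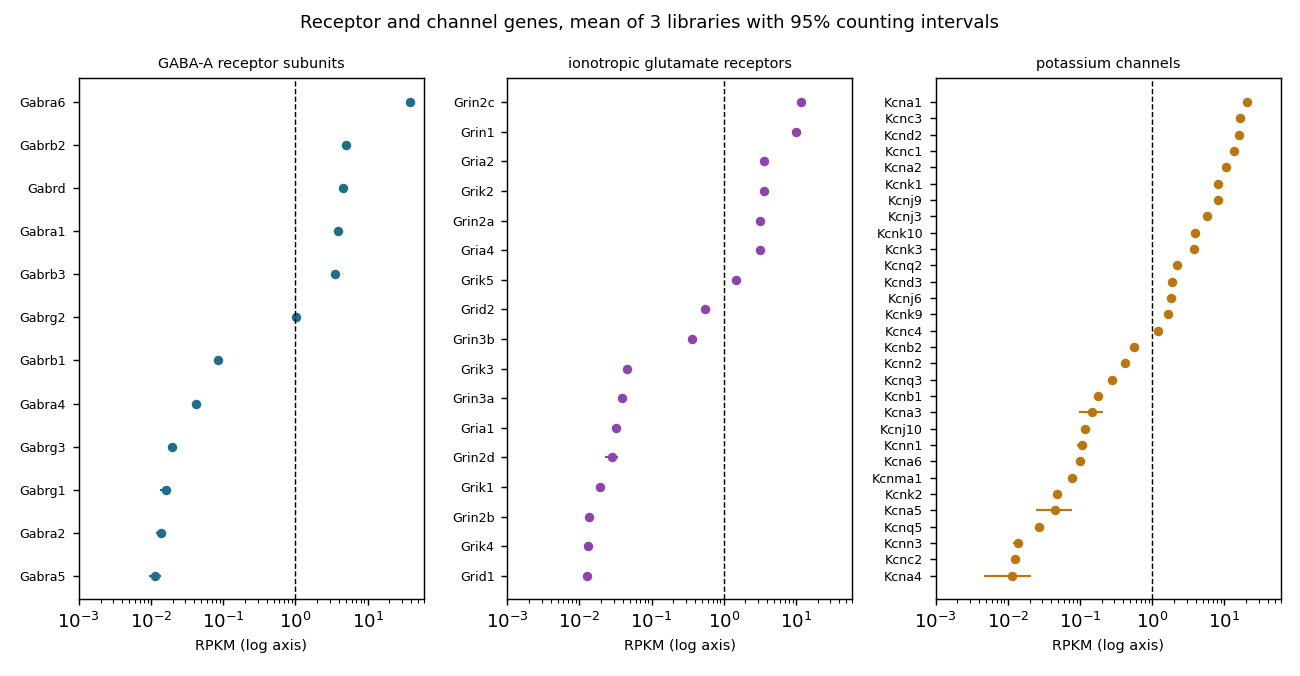
Points give RPKM on a log axis for GABA-A receptor subunit, ionotropic glutamate receptor and potassium channel genes, each as the authors' mean of 3 libraries. Horizontal lines are 95% Poisson intervals (counting error only) and the dashed line marks 1 RPKM. Gabra6 at 38.6, Grin2c at 11.8 and Kcna1 at 20.8 RPKM lead the 3 panels.

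Nuclear noncoding RNAs and splicing factors were among the highest of the other lists. The 11 measured long noncoding RNAs had a median of 3.50 RPKM at percentile 100, with Malat1, Snhg11, Meg3 and Rian (7.22 RPKM) at the top, Neat1 at 0.394 and Rmst at 0.0157 RPKM. The 11 SR splicing factor genes had a median of 4.88 RPKM at percentile 100. Srsf2 stood at 31.8, Srsf5 at 30.9, Srsf1 at 14.4 and Srsf3 at 6.36 RPKM, and Srsf12 was the lowest at 0.439 RPKM. The 10 measured housekeeping genes had a median of 2.08 RPKM (percentile 99.97, and 87.5 among genes at 1 RPKM or more), led by Ubc at 15.9, Actb at 6.58, Eef1a1 at 5.69 and Eef2 at 4.69 RPKM, with Hmbs at 0.854 RPKM. Cytosolic ribosomal protein genes had a median of 1.06 RPKM over 76 measured members. Rpl10a, the gene carried by the sort transgene (chromosome 17, 28328471 to 28331033, plus strand), stood at 14.02 RPKM (13.6 to 14.5), against 4.04 RPKM for the next gene, Rpl41, 3.42 for Rpl36, 2.91 for Rpl9 and 0 for Rpl10l. Nuclear-encoded respiratory chain genes had a median of 1.46 RPKM over 72 members, with Atp5b at 10.4, Cox7c at 4.78 and Ndufv2 at 3.62 RPKM and Cox6a2 listed at 0. Proteasome core genes had a median of 1.03 RPKM over 19 members, with Psma3 at 2.36 and Psmb4 at 2.15 RPKM, and Psmb8 at 0.00267 RPKM. These last 3 lists lay at percentiles 100, 100 and 99.3 of all random lists, and at 6.48, 20.8 and 11.96 among genes at 1 RPKM or more.

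Genes of the circadian clock had a median of 1.44 RPKM over 12 members, at percentile 99.8 (30.3 among genes at 1 RPKM or more), with Nr1d2 at 3.09, Nr1d1 at 2.88, Clock at 2.08 and Per3 at 2.08 RPKM and Npas2 lowest at 0.0443 RPKM. Immediate early genes, which are induced by activity, had a median of 0.667 RPKM over 17 members, at percentile 93.4, and 3 reached 1 RPKM. The list lay at 98.2 of lists matched on span, at 70.6 with the mean over members and at 17.85 among genes at 1 RPKM or more. Dusp1 stood at 4.73, Egr1 at 1.33 and Nr4a1 at 1.04 RPKM, with Egr3 at 0.00633 RPKM. Of 9 heat shock genes (median 0.557 RPKM, percentile 81.4, and 98.7 with the mean over members), the constitutive chaperone gene Hspa8 stood at 19.4, Hsp90aa1 at 5.70 and Hspd1 at 1.78 RPKM. The inducible chaperone gene Hspa1a stood at 0.0263 RPKM, and Hspa1b and Hspb1 were listed at 0.

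Hox, olfactory receptor and vomeronasal receptor genes were mostly at or near 0. None of the 39 Hox genes (median 0.00267 RPKM) reached 0.1 RPKM, with Hoxb1 highest at 0.0197 RPKM and 16 listed at 0. Among 1095 olfactory receptor genes, 972 were listed at 0 and 3 reached 1 RPKM, Olfr239 at 2.16, Olfr55 at 1.62 and Olfr543 at 1.03 RPKM. Of 327 vomeronasal receptor genes 197 were listed at 0, and Vmn2r29 was highest at 0.651 RPKM. The median of each receptor family was 0, and all 3 lists lay at percentile 0 of random lists. Against lists matched on span, whose typical median was also 0, the olfactory receptors stood at 49.99. That value is a tie of 0 with 0 and does not place them. Clustered protocadherin genes had a median of 1.08 RPKM over 58 members at percentile 100, with Pcdhgb6 highest at 5.68 and Pcdhb1 lowest at 0.00433 RPKM. Of these, 56 lie inside the span of another gene, so their values share reads and are not independent. Replication-dependent histone genes had a median of 0.128 RPKM over 64 members, at percentile 40.1, with Hist2h2be at 2.31 and Hist1h4d at 1.89 RPKM. The 104 small nucleolar RNA genes had a median of 0.674 RPKM at percentile 100, of which 95 lie inside another gene. Snora23 stood at 15.0 RPKM. Of 963 microRNA genes (median 0 RPKM, percentile 0) 496 were listed at 0 and 198 reached 1 RPKM, and 668 lie inside another gene. The last 3 lists hold very short genes and moved with the treatment of gene length, and with means over members histones lay at 0.01 and microRNAs at 12.7. Small nucleolar RNAs crossed to percentile 0 when values were not divided by span. MicroRNAs crossed to 100 among genes above 0 and to 99.98 among genes at 1 RPKM or more.

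Very long genes carried reads as well. Median levels went from 0.026 RPKM in genes with spans under 10 kb to 0.306 RPKM at 10 to 30 kb, 0.416 at 30 to 100 kb and 0.428 at 100 to 300 kb, and stood at 0.346 RPKM in 479 genes over 300 kb. The share of genes at 1 RPKM or more was 17.3% in the shortest class and 30.9% in the longest. Families with many genes at 0, such as microRNAs (496 of 963) and olfactory receptors (972 of 1095), were not left out. Their part in these differences, and in the correlation over all genes below, was not examined. Among genes over 300 kb the highest were Kcnd2 at 16.2, Fgf14, a modulator of sodium channels, at 9.61, the splicing regulator gene Rbfox1 at 7.53 and Nrxn1 at 6.25 RPKM. These long genes were named after their values were seen. Across genes, which are not independent replicates, Spearman's rho of RPKM and span was 0.33 over all 22595 genes and -0.03 over the 5391 genes at 1 RPKM or more, a subset chosen on the level itself.

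By chromosome, the share of genes at 1 RPKM or more ranged from 17.8% on chromosome 7 to 33.2% on chromosome 18. Chromosome 7 holds 389 olfactory and vomeronasal receptor genes, and without such genes its share was 21.7%. Chromosome 18 holds the clustered protocadherins, and without them its share was 29.3%. Without receptor genes, chromosome 13 stood lower than chromosome 7, at 20.3%. Chromosomes 12 and 2 then stood at 28.3% and 28.2%, close to chromosome 18 without protocadherins. The median level of genes at 1 RPKM or more was 1.79 RPKM on chromosome 7 and 1.82 RPKM on chromosome 18. Genes of the X, Y and mitochondrial chromosomes were not analysed here, and neither the X to autosome ratio nor the Y-linked and mitochondrial lists were computed.

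The authors' deposited table of their comparison of Dnmt3a conditional knockout and wild-type granule cell nuclei gives an effect size per transcript, with no sign, no p-value and no definition in the sources used here. In the authors' deposited table the effect size of Dnmt3a itself was 0.747, at percentile 82.2 of all genes. Among the 200 genes nearest to Dnmt3a in RPKM of the 3 libraries, the authors' deposited table placed it at percentile 50, beside a median effect size of 0.746. The highest effect sizes in the authors' deposited table were those of Rn45s (62.7), Mir6236 (32.2), Malat1 (24.6), Gm20594 (24.0) and Mir684-1 (12.4), chosen after the values were seen. Across genes, Spearman's rho between the effect size in the authors' deposited table and RPKM in the 3 libraries was 0.85 over all genes and 0.53 over genes at 1 RPKM or more. No gene was called changed from the authors' deposited table.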

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

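Genes on scaffolds not placed in an assembled chromosome take part in no comparison by chromosome, yet 5 of 12 such genes, all on chromosome 4 scaffolds, stood at 1 RPKM or more, above the level that 3 reads would give. Gm10591 stood at 7.96 RPKM, Ccl21b at 7.65 RPKM and Gm13298 at 4.09 RPKM on the same scaffold. Gm1987 at 2.05 RPKM and Ccl21a at 2.05 RPKM lay on another. Gm1987 (1134 bp, 220 reads) and Ccl21a (1132 bp, 219 reads) were alike in span and reads and may not be separate measurements. The same may hold for Gm10591 (1131 bp) and Ccl21b (1095 bp). The Ccl21 genes have near-identical copies, so the assignment of their reads is uncertain, and no explanation was tested.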

How the results depend on the processing

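The settings with the shortest or highest transcript of each gene, merged loci kept, nested members left out, receptor or protocadherin genes left out and random lists matched on span were chosen after seeing the data. Leaving out each replicate, agreement and variation between libraries, median-ratio scaling, expression in every library, the X to autosome ratio, the Mecp2 differences and the adjusted p settings of the Dnmt3a comparison were not run, since the values are a pooled mean of autosomal genes with no p-value. No paired analysis was possible because the files hold no value per library and there is 1 group. Depth limits the lowest genes, and the variation between libraries stays unknown. Unless a value or the construction of a setting shows it, the cause of each move below was not tested.

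The number of genes expressed moved to 12007 at a floor of 0.1 RPKM and to 434 at 5 RPKM, as a lower or higher floor must. It stayed within 1.5 times of the main count in the other 3 settings. The granule cell list stayed above each of the 13 other cell type lists in all 91 settings computed. Of these, 57 lay within the 95% bootstrap interval of the main difference over list members (2.46 to 4.06 for progenitors, for example). Part of this was fixed by construction, since a change of pseudocount keeps the order of genes. Leaving out nested members changed only lists that hold such members. With a pseudocount of 0.1, which compresses low values less, the log2 difference rose to 6.61 for progenitors, 4.55 for Purkinje cells, 6.39 for interneurons, 5.23 for astrocytes, 6.10 for oligodendrocytes, 6.23 for their precursors, 6.28 for microglia, 6.54 for endothelial cells, 4.67 for red blood cells, 6.16 for choroid plexus and 6.62 for forebrain neurons. With a pseudocount of 0.01 the same differences were 9.13, 4.85, 8.15, 5.77, 7.35, 7.73, 7.81, 8.76, 5.01, 7.49 and 9.18. Not divided by span, they were 7.45, 4.65, 5.95, 6.39, 6.61, 7.64, 6.87, 7.47, 7.48, 6.35 and 7.61, and the difference from newborn granule cells was 5.04.

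Within gene families no direction changed, but a change of pseudocount cannot reverse one. The choice of transcript left the Tet3 differences as they were. The log2 difference of Dnmt3a over Dnmt1 was 1.09 and 1.18 with pseudocounts of 0.1 and 0.01, 2.19 not divided by span, 0.989 with the highest and 0.996 with the shortest transcript. Over Dnmt3b it was 2.58, 2.99, 4.38, 1.64 and 1.64 in the same order. Tet3 exceeded Tet1 by 1.58, 1.69 and 1.76, and Tet2 by 1.31, 1.39 and 1.36, with the pseudocounts and not divided by span. The correlation of level with gene span turned from 0.33 to -0.031 among genes at 1 RPKM or more, a subset chosen on the level itself, and rose to 0.70 not divided by span, where longer genes hold more reads. The excess of chromosome 18 over chromosome 7 in the share of genes expressed, 15.4 percentage points, was 2.70 at a floor of 5 RPKM, 11.5 without receptor genes, 11.5 without protocadherins and 7.63 without either. The difference of their median log2 levels, 0.01, was 0.45 over all genes, 0.22 at a floor of 0.1 RPKM and -0.46 at 5 RPKM.

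Of the percentiles of the gene lists, 256 stayed inside or outside the outer 2.5% of random lists, 19 came to stand apart, 21 ceased to, and 9 of lists that stood apart crossed the middle of the random lists. A further 15 crossed the middle in lists that had not stood apart, such as metabotropic glutamate receptors, from 15.6 to 95.8 not divided by span. Among genes at 1 RPKM or more, which leaves only members above that floor, 7 lists that had stood apart crossed: methyl-CpG readers to 48.1, MeCP2 partners to 37.8, clock genes to 30.3, ribosomal proteins to 6.48, respiratory chain to 20.8, proteasome to 11.96 and microRNAs to 99.98. Immediate early genes, which had not stood apart, moved from 93.4 to 17.85. In that setting the TET and base excision list fell to 51.7, housekeeping genes to 87.5 and small nucleolar RNAs to 77.8. Olfactory receptors moved to 39.7, while ionotropic glutamate receptors reached 99.1, GABA-A receptors 99.6 and heat shock genes 98.98. Among genes above 0, microRNAs crossed to 100 and the TET and base excision list stood at 95.9. Forebrain neurons stood there at 7.77 and endothelial cells at 0.84. Not divided by span, small nucleolar RNAs crossed to 0 and histones fell to 0, since these genes are short. Progenitors then stood at 11.9, forebrain neurons at 6.58, ribosomal proteins at 77.1, the proteasome at 95, GABA-A receptors at 99.88 and sodium and calcium channels at 100. With means over members, progenitors stood at 2.58, interneurons at 0.11, unipolar brush cells at 96.2, oligodendrocytes at 1.37, their precursors at 1.77, endothelial cells at 0.17, ionotropic glutamate receptors at 99.33, GABA-A receptors at 99.85, sodium and calcium channels at 99.34, heat shock genes at 98.7, the proteasome at 95.02, histones at 0.01 and microRNAs at 12.7. Random lists matched on span were drawn anew here. They differ slightly from the draw behind the other percentiles matched on span (94.96 for the TET and base excision list). With them, unipolar brush cells stood at 97.15, endothelial cells at 2 and the TET and base excision list at 95.04. Immediate early genes stood at 97.98, olfactory receptors at 49.99, histones at 99.97 and microRNAs at 50. The values of olfactory receptors and microRNAs are ties of a median of 0 with 0, so they place neither list. The TET and base excision list stood at 97.3 with either pseudocount and at 97.1 with the highest transcript.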

Other observations

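The genes of this part, and the tests on the transgene of Rpl10a and on the slope of effect size with span, were chosen after the values were seen. Levels differed widely between members of several gene families, some of whose members (Zic1, Zic2, Zic4, Neurod1, Cbln1 and Cbln3) also stand in the granule cell list. Zic1 stood at 13.97 RPKM and Zic2 at 6.23 RPKM, against 1.05 for Zic5. The engrailed gene En2 stood at 5.02 RPKM and En1 at 0.1003 RPKM. Meis1 stood at 3.16 RPKM and Meis2 at 0.007 RPKM. Neurod2 stood at 5.37 RPKM beside Neurod1 at 21.4, while Neurod4 was listed at 0. All 4 nuclear factor I genes were transcribed, from 1.47 RPKM for Nfic to 4.08 RPKM for Nfib. Among pentraxin genes Nptx1 stood at 22.9 RPKM and Nptx2 at 0.00367 RPKM. Cbln3 exceeded Cbln1 by 2.32 times, while Cbln2 stood at 0.00633 and Cbln4 at 0.026 RPKM. Among 5 granin and secretory genes, all at 1 RPKM or more, Chgb was highest at 26.1 RPKM and Chga lowest at 1.61 RPKM.

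Of 7 sodium-potassium ATPase genes, 5 reached 1 RPKM. The neuronal α3 gene Atp1a3 stood at 16.6 RPKM and Atp1a1 at 13.3 RPKM, against 0.431 for the glial α2 gene Atp1a2. The chloride extruder gene Slc12a5 stood at 5.59 RPKM, the chloride importer gene Slc12a2 at 3.37 RPKM and Slc12a6 at 2.29 RPKM. Kcnip4 (5.62 RPKM), Dpp6 (5.24 RPKM) and Kcnip3 (2.38 RPKM), partners of Kv4 channels, stood beside Kcnd2, while Kcnip1, Kcnip2 and Dpp10 stood at 0.390, 0.151 and 0.505 RPKM. In the imprinted Dlk1-Dio3 region, the maternally expressed noncoding genes stood at 31.8 RPKM (Meg3), 7.22 RPKM (Rian) and 3.50 RPKM (Mirg). The protein-coding genes stood at 2.39 RPKM (Rtl1), 0.0227 RPKM (Dlk1) and 0.00567 RPKM (Dio3). Strand settings are not given, so antisense reads at Rtl1 cannot be told apart from its own. Ackr1, a gene better known from blood vessels and red cells, stood at 56.6 RPKM, 2.44 times the level of Cadm3, whose 3' end lies 750 bp upstream on the same strand.

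Genes that lie inside another gene carried reads that followed the surrounding gene. Over 1534 nested genes, Spearman's rho with the surrounding gene was 0.726 ± 0.0144 (bootstrap SD over genes), against 0.246 with the nearest gene outside it. This meets what reads of the surrounding gene would give, but it does not show which gene made the reads. The surrounding span includes the nested one, so reads over the nested gene can count in both. A gene outside shares no such reads. Where several genes surround a nested gene, the highest was taken. For 557 nested genes on the opposite strand, rho with the surrounding gene was 0.784, against 0.173 with the nearest gene outside, as counting without strand would give. The values of Timp4 inside Syn2 and of P2ry12 inside Med12l, markers of astrocytes and microglia, may therefore hold reads of the neuron's own transcripts. Shared regulation of overlapping genes stays open, and no biological explanation was tested, since the design holds 1 group.

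The effect size of the authors' deposited table rose with RPKM. The rank correlation with span at fixed RPKM was -0.273, which argues against a statistic that grows with the number of reads. The slope of log2 effect size on log2 span at fixed RPKM was -0.0540 ± 0.0031 (SE). Counting noise of an absolute difference would give -0.5, so this slope argues against such noise alone. In the same fit the slope on log2 RPKM was 0.522 ± 0.0090 (SE), of the size that such noise would give. Noise between libraries was not examined, so noise as the main content stays open. An absolute rather than relative scale stays open. The slope of log2 effect size on log2 RPKM over 5379 genes was 0.540 ± 0.0092 (SE), between the values set in advance for and against it. No biological explanation was tested.

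Rpl10a stood above the other ribosomal protein genes. A short span did not account for it, since 32 ribosomal protein genes with spans within 30% of that of Rpl10a had a median of 1.13 RPKM, 0.0806 times its value. Reads of an overlapping gene are argued against too, since no other gene of the table overlaps it, giving a ratio of 0. Transcripts of the EGFP-Rpl10a transgene stay open and cannot be told apart from higher transcription of the endogenous gene, since their reads were not separated. The ratio of Rpl10a to the highest other gene, 3.47, restates the pattern and decides nothing. No biological explanation was tested.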
